A study of Mus musculus with 6 samples.

How the data were processed

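Gene expression was measured in hearts dissected from mouse embryos at embryonic day 11.5, on 6 single-colour CodeLink arrays, each hybridised with biotin-labelled RNA. Per the labels, 3 arrays held RNA of hearts in which Dicer had been inactivated by a Cre recombinase placed in the Nkx2.5 locus, and 3 held RNA of control hearts. The genotype of the controls is not given in the sources used here. Groups were taken from the labels' descriptions, and replicates were numbered within each group. The labels do not say whether the arrays of a group came from separate embryos, pools or litters. The p-values therefore measure only the spread between these samples, which may be partly technical. Xist and the Y-linked Eif2s3y, given below, differed within each group in opposite directions, so a group's arrays did not all hold the same RNA.

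Each array's deposited file holds the mean pixel intensity of every spot, the median intensity of its local background, a background-subtracted intensity, a normalized intensity and a quality flag. Checked on the values, the subtracted intensity equalled the spot mean minus the background median, with a largest difference of 1e-04. The ratio of the subtracted to the authors' normalized intensity had a median per array between 66.1 and 82.8, over spots with a normalized value above 1. Whether that ratio was constant within an array was not checked. The series' value table held those normalized intensities on spots flagged good and was blank elsewhere. Its column medians lay between 1.83 and 2.06 on a linear scale, which was read from the comparison with the subtracted intensity. The scanner and its software are not given in the sources used here. Each array carried 36227 spots. The platform annotation listed 21880 of them with a gene: 21676 with 1 gene and 204 with several, from which no gene was named. The other 14347 spots are unnamed here, and control spots were not marked among them, so the tests used the listed spots. The design had foreseen that control spots would be left out by their mark. Symbols were checked against RefSeq genes of mouse assembly GRCm38.p6 through the gene number, which matched 21541 spots and changed 0 symbols. No coordinates are printed because the files name no build.

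Spot means were background-corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3, put on the log2 scale and quantile-normalized between arrays. A probe was tested when the scanner flag placed it above background on at least 3 of the 6 arrays, in whichever group, which left 17727 probes of 15012 genes. Between 26833 and 28345 spots per array (74.1% to 78.2%) were above background, and between 184 and 263 were saturated. The number of arrays limits the precision of each value. The 2 groups were compared with lmFit and eBayes, two-sided, without a block, and adjusted by the Benjamini-Hochberg method over all probes tested. A probe passed at an adjusted p under 0.05. For a gene with several probes the brightest was used, and the other probes tested for a named gene are given beside it. Log2 differences are mutant minus control, and normexp with an offset pulls those of dim probes towards 0.

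The 26 gene lists, the test, the naming rule and the alternatives were fixed before the data were examined. Lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, and adjusted over the 26 lists. Camera compares a list with all other genes, and fry asks whether its genes move one way on balance. Members were also adjusted over the list alone. The known miRNA targets were listed from general knowledge, without a database. Named genes are Dicer1, Nkx2-5 and Sema3c whatever their values; a further gene of this part of the rule is not reported here. Added to these are up to 12 genes per direction with the largest change among those that passed and whose groups did not overlap, clone names left out. Where fewer passed, the genes of that direction with the smallest p among those that did not overlap filled the 12 and are said not to pass. From each list up to 4 passing members were named, or otherwise the 2 with the smallest p, as values. Members that passed only over their list alone are named where a count is given, and were chosen after their values were seen. A planned test of miRNA seed matches in 3' untranslated regions was not run, because it needs transcript sequences, which were not used here.

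The test was tried on simulated data for this comparison: 17695 probes with the real means and spreads, 200 of them changed. Of those changed 2-fold, 62% were called, and of those changed 4-fold, 95%, with 4.8% of calls made on unchanged probes. The simulation drew probes independently, unlike real arrays. It also planted 200 changed probes, whereas 9 probes passed in the real data. More calls loosen the Benjamini-Hochberg cutoff, so the 62% and 95% may overstate how often a real change of that size was called. Also computed, as fixed beforehand, were median centring, cyclic loess, the floored subtracted intensity, a normexp offset of 10, the authors' normalized intensity, the series' value table, other filters on dim probes, the number in the middle of the array titles as a block, the slide as a block (inferred from the start of the titles, since the labels name none), a trended and robust variance, array weights, flagged spots left out, a per-probe test with unequal variances, the mean over a gene's probes and leaving out arrays. Testing all spots and adding a residual component as a covariate were chosen after seeing the data. Figures were drawn with matplotlib in Python.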

Results

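Gene expression was compared between hearts of mouse embryos lacking Dicer in the Nkx2.5-Cre lineage and control hearts at embryonic day 11.5, with 3 arrays per group. Dicer is the ribonuclease that cuts miRNA precursors into mature miRNAs, and Nkx2-5 is a transcription factor gene active in cardiac progenitors. The comparison asks which transcripts differ in level when the enzyme is inactivated in the developing heart. Each array measured 36227 spots, of which 74.1% to 78.2% were above background, and 17727 probes entered the test.

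Dicer1 itself was lower in the mutant hearts, at 6.72 ± 0.03 against 7.72 ± 0.10 on the log2 scale (SD, n = 3 each), which is 0.498 of the control level (95% interval 0.429 to 0.579, limma adjusted p = 0.036). The log2 difference was larger, -1.61, with the authors' normalized intensity, which carries no offset. All 3 mutant arrays lay below all 3 control arrays. The signal was low, although flagged above background on all 6 arrays, and the position of the probe (number 31325) relative to the deleted part of the gene is not known here. A probe outside that part would not check the labels. Nkx2-5, whose locus carries the Cre, gave a log2 difference of -0.23 ± 0.21 (SE, adjusted p = 0.73). That difference turned positive with the slide, inferred from the array titles, as a block, at 0.22, and without mutant 3 and control 3, at 0.013.

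In total 9 probes passed limma's test, 5 higher and 4 lower in the mutant, each the brightest probe of its gene. Tnnt1, the slow skeletal troponin T, fell to 0.216 of the control level (95% interval 0.163 to 0.287). Its log2 signal was 9.65 ± 0.20 in the mutant and 11.86 ± 0.27 in the control (SD, n = 3 each). Thbs4, an extracellular matrix thrombospondin, rose by 1.64 ± 0.14 (log2 difference ± SE), or 3.13-fold. Nr6a1, a nuclear receptor repressed by let-7, rose by 1.33 ± 0.10, or 2.52-fold. Of the RNA-binding splicing regulators, Qk rose by 1.57 ± 0.14 and Celf1 by 1.24 ± 0.11. The dimmer probe of Qk gave -0.01 and that of Celf1 0.32, neither passing, and the mean of both Qk probes gave 0.78. Ttpal fell by 1.72 ± 0.16, although its dimmer probe gave -0.03. Its difference ranged from -2.76 with the authors' normalized intensity to -0.88 with the mean of its probes. Nts, which encodes the peptide neurotensin, fell by 1.03 ± 0.10. The ninth, the clone-named 5430431A17Rik, rose by 1.16 ± 0.10. The adjusted p was 0.036 for these probes except Nts, at 0.0474.

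**Figure D1:**
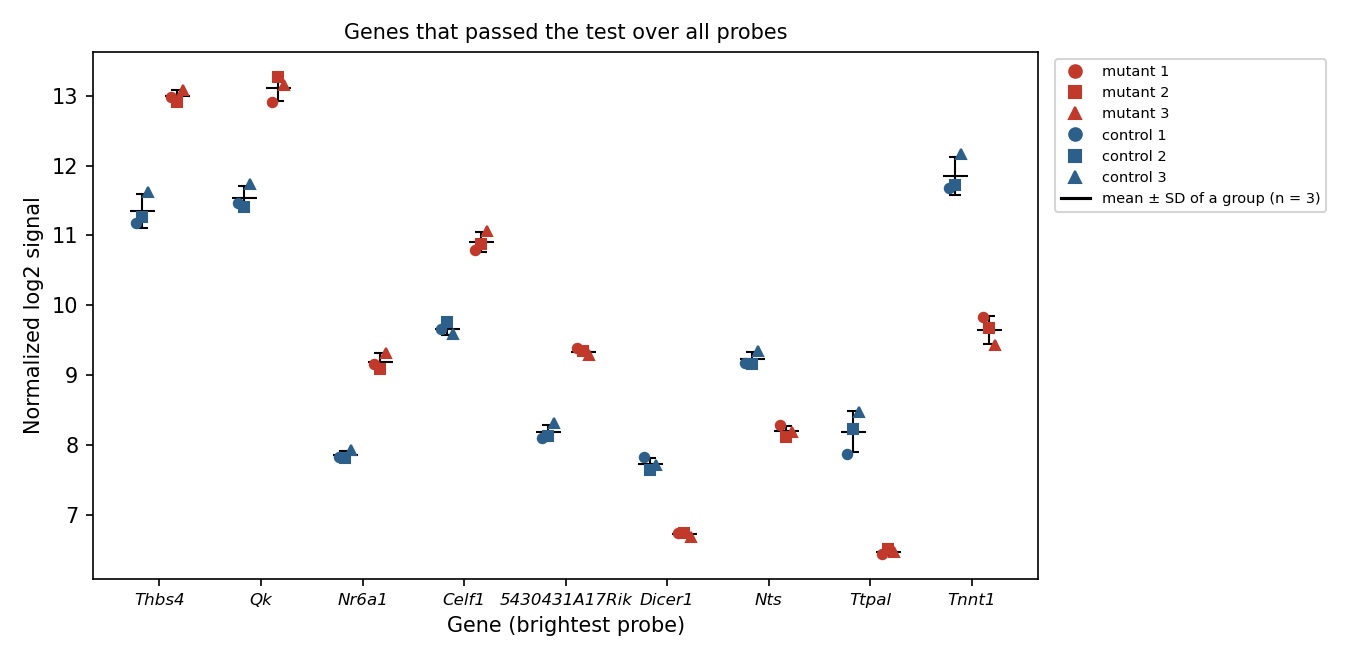
Normalized log2 signal (y axis) of the 9 genes that passed the test (x axis), with a point per array and the mean ± SD of each group. In each gene all 3 mutant arrays lie on one side of all 3 control arrays; Dicer1 lies at 6.72 in the mutant mean and 7.72 in the control mean.

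At an unadjusted p under 0.05 there were 1775 probes, 1197 higher and 578 lower, against 886 expected by chance. Probes are not independent, which widens the spread of such a count. The other splits of the 6 arrays into 3 and 3 gave 53 to 4626. The groups did not overlap in 2685 probes (15.2%, with 10% from chance for 3 against 3). The count of 9 changed with each array left out. Without control 3, 320 probes passed, 119 higher and 201 lower, and the 9 were among them. Without mutant 1, mutant 2, control 1 or control 2 limma called 0 probes, with 1417, 1199, 1317 and 842 at an unadjusted p under 0.05. Without mutant 3 it called 1 probe, with 2746, and that probe was not among the 9. The labels name no slide. The start of the array titles was read as its barcode, which put mutants 1 and 2 on a slide with control 1 and the other arrays on slides of their own. With the slide so inferred as a block, which compares those 3 arrays alone and takes control 1 to vary like the mutants, 1338 probes passed, 534 higher and 804 lower.

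The arrays differed in a way that the groups did not follow. The first principal component, with 54.1% of the variance, placed control 1 at 37.3 and control 2 at 26.3, mutant 3 at 5.63, and mutant 1, control 3 and mutant 2 at -18.3, -20.8 and -30.1. The second, with 21.6%, set mutant 3 apart at -34.8. Across probes, control 3 correlated with mutants 1 and 2 at 0.979 and 0.984, and with controls 1 and 2 at 0.955 and 0.971. Genes are not independent replicates in these correlations.

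**Figure D2:**
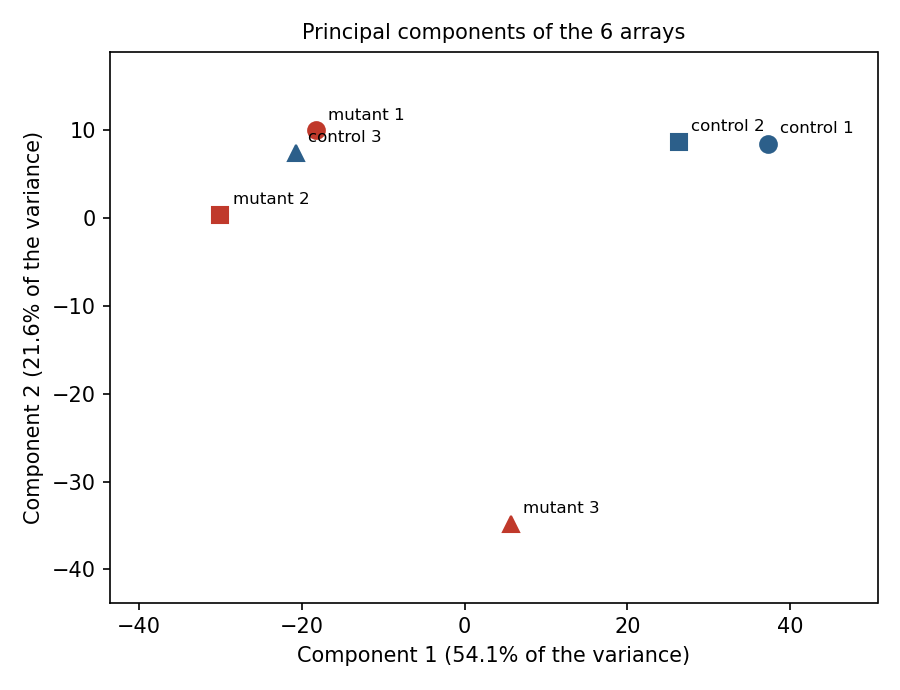
Scores of the 6 arrays on the first (x axis) and second (y axis) principal component of the normalized log2 signals, without units, coloured by group. Control 3 (-20.8) lies beside mutants 1 and 2 on the first component, and mutant 3 lies alone on the second (-34.8).

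The genes named next did not pass. They were picked, clone names left out, by the smallest p among genes whose groups did not overlap. On the higher side, Masp1, a serine protease of the complement lectin pathway, gave a log2 difference of 1.81 ± 0.20 (SE) with an adjusted p of 0.0789. The basement membrane gene Nid2 gave 0.85 ± 0.09 and the matrix gene Spon1 0.79 ± 0.08, both with an adjusted p of 0.0686. Art3 gave 1.27, Zbtb20 1.27, Camta1 0.92, the integrin Itgav 0.91 and Gfpt2 0.65, with adjusted p from 0.0717 to 0.0836. The dimmer probe of Camta1 gave -0.84, that of Masp1 0.53 and that of Spon1 0.55, and those of Zbtb20 0.46, 1.3 and 0.18. On the lower side, the diacylglycerol kinase Dgkk gave -1.02 ± 0.12 and the transcription factor Nfix -1.05 ± 0.14, with -0.01 for a dimmer probe of Nfix. Ttl, a tubulin tyrosine ligase, gave -1.65 ± 0.24, and its dimmer probes -0.09 and -0.02. Bex1 gave -0.87, Myl3 -0.78 (dimmer probe -0.98), Spink2 -0.77, Tceal5 -0.75 and Cdkl1 -0.73. Adjusted p for the lower side ran from 0.0812 to 0.115.

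Several known let-7 targets were higher in the mutant, although 12 of the measured members had a negative difference, against 17 with a positive one. Of 29 measured members, 1 rose and 1 fell over all probes tested: Nr6a1, and Dicer1, the gene inactivated in the mutant. Adjusted over the list alone 5 rose and 1 fell. The others were Trim71, a developmental ubiquitin ligase (1.14 ± 0.26, SE), Arid3b (0.72 ± 0.17), the phosphatase Cdc25a (0.59 ± 0.16) and Lin28a, the RNA-binding repressor of let-7 maturation (0.57 ± 0.13). A probe of Lin28b, also on the list, fell by 1.14 with control 3 left out (limma adjusted p = 0.0446). The list's median was 0.06 and camera did not call it (adjusted p = 0.572). Targets of the miR-17, miR-19 and miR-15 families were higher as a list by camera: 22 of 30 members had a positive difference, with a median of 0.19 (adjusted p = 0.0296, and adjusted p = 0.692 with an estimated correlation). No member passed over all probes. Over the list alone Cdkn1a, the cell cycle inhibitor p21, rose by 1.49 ± 0.27. Stat3 gave 0.44 ± 0.11 and its dimmer probes 0.92 and 0.91. Fry gave the list an adjusted p of 0.00248. Camera's call was also lost without mutant 1, mutant 3 or control 3, at 0.0887, 0.069 and 0.117. Targets of miR-1, miR-206 and miR-133 had a median of 0.01 over 33 members (adjusted p = 0.963), and camera's direction was down where the median was positive. Over that list alone Cdc42 fell by 0.52 ± 0.10. Igf1 gave -0.40.

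Small RNA machinery was higher as a list by camera, with 16 of 20 members above 0 and a median of 0.19 (adjusted p = 0.0306, and adjusted p = 0.692 with an estimated correlation). Dicer1 fell over all probes. Over the list alone 3 members rose: Tnrc6a, which encodes a GW182 silencing protein, by 1.20 ± 0.20 (SE), Ago3, an Argonaute gene, by 0.69 ± 0.18 and the helicase gene Mov10 by 0.50 ± 0.12. The list's array medians were 0.18 and 0.20 in mutants 1 and 2, -0.04 in mutant 3 and 0.10 in control 3, so that mutant 3 lay below control 3. The call held without control 3 (adjusted p = 0.011) and was lost without any other array, at 0.0517 to 0.115. Among miRNA host genes and imprinted transcripts, whose 28 members had a median of 0.04 (adjusted p = 0.721), no member passed over all probes. Over the list alone 3 rose, Pank3 (0.69 ± 0.11), Ctdspl (0.43 ± 0.10) and Grb10 (0.41 ± 0.10, dimmer probe 0.10). The imprinted Dlk1 fell by 0.81 ± 0.21 (dimmer probe -0.34).

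Of 15 measured skeletal muscle genes, Tnnt1 fell over all probes, and adjusted over the list alone Tnnt3, the fast skeletal troponin T, rose by 2.63 ± 0.39 (SE, 6 arrays). Tnni2, the fast skeletal troponin I, rose by 0.80 ± 0.10 and the myosin light chain Mylpf by 0.35 ± 0.11 (dimmer probe 0.10), also over the list alone. The list as a whole had a median of -0.02 (adjusted p = 0.963). The 23 measured sarcomere genes had a median of 0.05 and a mean of -0.005, of opposite sign, and an adjusted p of 0.991. Over that list alone Myl3, the ventricular essential light chain, fell by 0.78 ± 0.10. Myom1 gave 0.62 ± 0.19, and the cardiac troponins Tnnt2 and Tnni3 gave 0.46 ± 0.19 and 0.41 ± 0.16. Of 25 mitochondrial and fatty acid metabolism genes, 0 passed over all probes. Over the list alone Mb, myoglobin, fell by 2.06 ± 0.32 and Ckmt2, the mitochondrial creatine kinase of muscle, rose by 0.73 ± 0.14. The median of that list was 0.14, its mean -0.06 and its adjusted p 0.762. Calcium handling, natriuretic peptide and conduction genes had a median of 0.12 over 18 members (adjusted p = 0.211). Over the list alone the sodium-calcium exchanger Slc8a1 rose by 0.66 ± 0.13 (dimmer probe 0.24) and the potassium channel Kcnq1 by 0.88 ± 0.22. Smooth muscle genes had a median of 0.10 over 13 members (adjusted p = 0.721), and calponin Cnn1 rose by 0.48 ± 0.11 over the list alone. Tpm2 gave -0.49 ± 0.27.

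**Figure D3:**
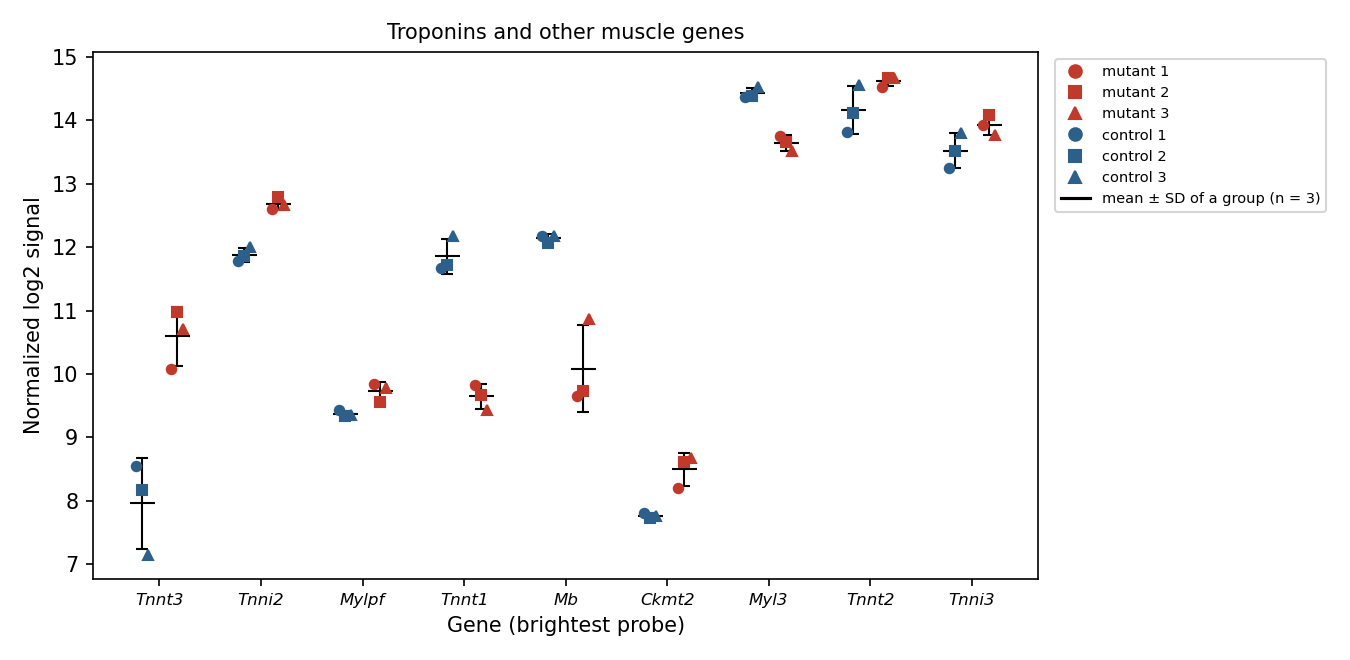
Normalized log2 signal (y axis) of troponins and other muscle genes (x axis), with a point per array and the mean ± SD of each group. Tnnt3 and Tnni2 lie higher in every mutant array than in every control array and Tnnt1, Mb and Myl3 lower; of these, Tnnt1 passed over all probes (log2 difference -2.21).

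Cardiac transcription factors were not called as a list, with a median of 0.05 over 28 members (adjusted p = 0.881), and no member passed in either adjustment. Irx4, a ventricular homeobox gene, gave 1.22 ± 0.29 and Hopx -1.04 ± 0.22 (log2 difference ± SE). Outflow tract and guidance signals had a median of -0.12 over 21 members (adjusted p = 0.342), with none passing. Sema3c, a semaphorin of the outflow tract, gave -0.42 ± 0.23 with an adjusted p of 0.579. Its levels were 8.80, 8.45 and 7.88 in the mutants and 8.96, 8.74 and 8.68 in the controls, and its dimmer probe gave -0.07. Slit2 gave -0.51 ± 0.22 (dimmer probe -0.43) and Plxnd1 -0.21 ± 0.11. Of 37 Bmp, Tgf-beta, Notch and Fgf pathway genes, 0 passed over all probes, and Fgf9, a growth factor for the myocardium, fell by 0.58 ± 0.10 over the list alone (dimmer probe -0.45). Bmp7 gave 0.53 ± 0.12 (dimmer probe 0.42). The list's median was 0.02, its mean -0.04 and its adjusted p 0.721.

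Camera called 3 lists lower that mark other cell types of the heart and its blood. Endocardium and endothelium genes lay below 0 in 17 of 22 members, with a median of -0.12 (adjusted p = 0.0296, and adjusted p = 0.692 with an estimated correlation). The array medians overlapped between the groups, with control 1 at -0.013 below mutant 2 at -0.008. No member passed, and Cd34 gave -0.35 ± 0.10 and Esam -0.28 ± 0.11 (SE). Cushion mesenchyme and matrix genes lay below 0 in 17 of 23 members, with a median of -0.24 (adjusted p = 0.0333, and adjusted p = 0.692 with an estimated correlation). The array medians were -0.20 in mutants 1 and 3 but 0.13 in mutant 2, within the controls' range of 0.09 to 0.14. Over that list alone the matrix genes Fbln1 and Vcan rose, by 0.71 ± 0.14 and 0.61 ± 0.13 (0.08 for the dimmer probe of Vcan), and Postn, periostin, fell by 0.56 ± 0.12. Erythroid genes lay below 0 in 13 of 14 members, with a median of -0.34 (adjusted p = 0.0296, and adjusted p = 0.692 with an estimated correlation), and none passed. Gata1 gave -0.68 ± 0.25 and Rhag -0.30 ± 0.17. The erythroid array medians did not follow the groups: 0.66 in control 1, 0.29 in control 2, 0.04 in mutant 1, -0.19 in mutant 3, -0.29 in control 3 and -0.38 in mutant 2. Without mutant 3 the 3 lists gave adjusted p of 0.069, 0.155 and 0.123. The endocardial call was also lost without mutant 1 (0.183) or control 3 (0.175), the cushion call without mutant 1 (0.0887), control 1 (0.0636) or control 3 (0.175), and the erythroid call without mutant 2 (0.149), control 1 (0.211) or control 2 (0.0695).

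**Figure D4:**
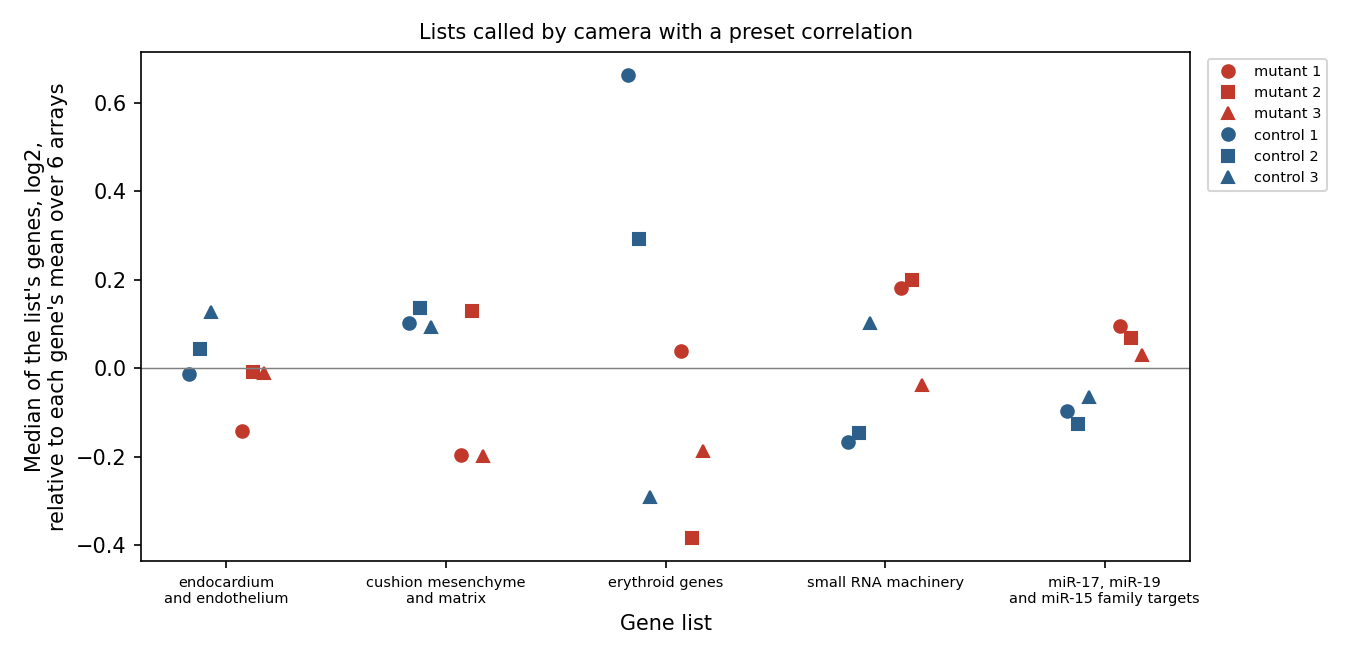
Median over the genes of each list called by camera (x axis) of the log2 signal relative to each gene's mean over the 6 arrays (y axis), a point per array. In the erythroid list control 3 (-0.29) lies among the mutants and control 1 (0.66) far above; in the miR-17, miR-19 and miR-15 target list every mutant lies above every control.

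The remaining marker lists were not called. Epicardial genes had a median of -0.14 over 12 members (adjusted p = 0.35), with Rspo1 at -0.86 ± 0.25 and Bnc1 at -1.21 ± 0.50 (log2 difference ± SE). Leukocyte and platelet genes had a median of 0.11 over 12 members (adjusted p = 0.343), with Ppbp at 0.62 and Cd14 at 0.38. Liver genes had a median of 0.05 over 6 members (adjusted p = 0.876), with Apoa2 at 0.21 and Trf at -0.33, whose dimmer probe gave 0.29. Foregut and lung bud genes had a median of 0.04 over 10 members (adjusted p = 0.709) and a mean below 0, with Krt5 at 0.28 and Sox2 at -0.74. Neural and neural crest genes had a median of -0.05 over 18 members (adjusted p = 0.721), with Ednrb at -0.49 and Ret at -0.60. Pharyngeal, limb and Hox genes had a median of -0.01 over 15 members (adjusted p = 0.572), with Hoxb6 at 0.46 and Hoxc5 at -0.30. None of these members passed in either adjustment.

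Growth and stress programmes were not called as lists in the main test. Proliferation genes had a median of 0.06 over 29 members (adjusted p = 0.256), with Cdc25a at 0.59 ± 0.16 and Ccna2 at 0.28 ± 0.09 (log2 difference ± SE), neither passing over that list. In the p53 and apoptosis list, with a median of 0.06 over 24 members (adjusted p = 0.572), Cdkn1a rose over the list alone and Pmaip1 gave 0.43 ± 0.19. Interferon and double-stranded RNA response genes had a median of 0.17 over 16 members (adjusted p = 0.151). In some other settings camera called this list higher, as with no filter (adjusted p = 0.0394) and without mutant 2 (adjusted p = 0.0127). Bst2, an interferon-induced membrane protein, rose by 0.98 ± 0.17 over that list alone, and Irf1 gave 0.30 ± 0.10. Hypoxia and glycolysis genes had a median of 0.07 over 24 members (adjusted p = 0.721), with Hk1 at 0.48 ± 0.19 and Pfkp at 0.61 ± 0.26. This list's array median was 0.44 in mutant 3, 0.11 in control 1 and between -0.21 and -0.03 in the other arrays. With the inferred slide as a block its direction turned down (adjusted p = 0.0221).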

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

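Testing all spots was chosen after the data were seen. It took in spots that the platform annotation lists with no gene and that no comparison above used. Of 10458 such spots above background on at least 3 arrays, 3 passed limma's test, 1 higher and 2 lower in the mutant, and 597 had an unadjusted p under 0.05. Over all spots 9 passed, so that 6 of the 9 listed probes of the main test kept their call and Ttpal, Thbs4 and Nts lost it, with adjusted p of 0.0535, 0.0535 and 0.0692. What these 3 spots measure is not known here, and control spots are not marked among them.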

How the results depend on the processing

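Leaving out both arrays of a title number and the other settings were planned, except the residual component as a covariate and the test of all spots, chosen after seeing the data. The 9 genes that passed kept their direction in all 26 alternatives run for each, and none of the genes named reversed a call. Of 234 such values 128 kept the call, and the rest lost it. Of 1610 values of named genes that did not pass, 190 gained a call, and 2 changed sign without a call, both of Nkx2-5.

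The number of changed probes, 9, moved to 5 with the subtracted intensity (2 higher, 3 lower), 4 with the authors' normalized intensity (1 higher, 3 lower) and 5 with the series' value table (2 higher, 3 lower). It was 1338 with the slide, inferred from the array titles, as a block and 7304 with array weights, which did not converge and put a weight of 151 on control 2. The residual component as a covariate gave 645, with p-values that are too small because the component was taken from the same residuals. The per-probe test with unequal variances called 0 (1209 at an unadjusted p under 0.05). Without 1 array the count ranged from 0 to 320. Without the arrays of a title number it was 0, 0 and 3919. Same-numbered arrays did not resemble each other: their deviations from the group means correlated at 0.014, -0.48 and -0.381. The highest correlation, 0.557, was that of mutant 2 and control 3. Such a structure can hide a smaller shared effect, so a pairing by title number stays open. With that number as a replicate block limma called 0 probes (1322 at an unadjusted p under 0.05) and 5 lists.

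The number of lists called, 5, moved to 2 with the authors' normalized intensity, 1 with the series' value table, 2 with array weights, 3 with the residual component, 0 with an estimated correlation and 1 with fry. Without 1 array it ranged from 0 to 4, and without the arrays of a title number it was 0 and 2 where it moved. Adjusted p without 1 array ranged from 0.0127 to 0.183 for endocardium, 0.0014 to 0.175 for cushion mesenchyme, 6.29e-05 to 0.211 for erythroid genes, 0.011 to 0.115 for small RNA machinery and 0.0127 to 0.117 for miR-17, miR-19 and miR-15 targets. With an estimated correlation it was 0.692 for all 5, and with fry 0.394, 0.394, 0.544 and 0.46 for the first 4. Endocardium and cushion mesenchyme gave 0.0624 and 0.0617 with the authors' normalized intensity, 0.0549 each with the series' value table, 0.462 and 0.425 with the slide block, 0.196 and 0.256 with array weights, and 0.0701 and 0.0645 with the residual component. Cushion mesenchyme gave 0.076 with the mean of a gene's probes. Small RNA machinery gave 0.0502 with the authors' normalized intensity and 0.0549 with the value table. The miR-17, miR-19 and miR-15 targets gave 0.0549 with the value table, 0.262 with the slide block and 0.196 with array weights. Without the first title number the lists in the above order gave 0.0826, 0.0826, 0.0558, 0.178 and 0.0826. Without the second, erythroid genes gave 0.351 and small RNA machinery 0.175. Without the third, endocardium and cushion mesenchyme gave 0.248 each and the miRNA targets 0.128. Lists not called in the main test gained a call in some settings. The interferon list was called higher with no filter (0.0394, for 6 lists in all), without mutant 2 (0.0127, 4 lists, 3 of them among the 5) and without the second title number (0.00856, also 4 and 3). The slide block called 4 lists, of which 2 were among the 5; the others were sarcomere genes (0.0112) and hypoxia genes, which reversed (0.0221). Fewer arrays were tested in the left-out settings, and for the others the cause was not tested. Not run were the alternatives for miRNA seed matches. Probes near background are limited by signal over background.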

Other observations

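All tests in this part were chosen only after the results they bear on were seen. Stress-linked genes, named here after their values were seen, varied strongly between arrays of the same group. Ddit3, a transcription factor of the integrated stress response, stood at 12.14, 11.86 and 11.70 (normalized log2 signal) in mutant 3, control 1 and control 2, and at 9.79, 10.11 and 9.86 in mutant 1, mutant 2 and control 3. The inducible heat shock gene Hspa1b stood at 10.95, 10.74 and 10.32 in the former arrays and at 8.45, 8.96 and 8.88 in the latter. Vegfa stood at 10.92, 10.07 and 9.67 against 9.09, 9.15 and 8.90, in the same order of arrays. Atf3 was highest in control 1 and control 2, at 11.22 and 10.85, then mutant 3 at 9.33, and lay between 6.97 and 7.98 in the other arrays.

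A structure of the samples showed in the other splits of the 6 arrays. Of the 10 splits into 3 and 3, 2 gave at least 9 changed probes, the real one included, and the highest other gave 1121, setting mutant 1, mutant 2 and control 3 against the rest. For the lists called by camera, 3 of the 10 splits gave at least the 5 of the real one, and the highest other gave 6. With 10 splits a share under 0.05 cannot be reached. Dicer1 lay 1.03 higher in control 3 than in mutant 3, as their labels have it. It stood at 6.74, 6.73 and 6.68 in mutants 1, 2 and 3 and at 7.82, 7.63 and 7.71 in controls 1, 2 and 3. Each of these arrays thus lay with its labelled group, which argues against an exchange if the probe reports the deletion. The probe is dim and its position relative to the deleted part is not known, so an exchange of these arrays stays open. Blood stays open too: controls 1 and 2 had the highest erythroid medians, but that of mutant 3 lay below that of mutant 1, by a difference of -0.225 that rests on 1 array. Whether a stress response before lysis underlies part of the structure stays open, since the stress genes named above were picked for this pattern. The medians of 23 further stress genes gave -0.085 for the lowest of mutant 3, control 1 and control 2 minus the highest of the others, too near 0 to decide. Single genes among them went both ways. Asns and Ppp1r15a were higher in mutant 3, control 1 and control 2 than in every other array, and Hspa5 and Dnajb1 were lower. A difference in embryo stage or litter was not tested.

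The fast skeletal troponins Tnnt3 and Tnni2 were higher and Tnnt1 lower in the mutant hearts. Skeletal muscle carried along in the mutant dissections would bring its other abundant transcripts too. The other measured skeletal muscle genes did not rise as a set. The 9 with a mean signal of at least 7, among them Tnnt1, had a median change of -0.132 (SD 0.807 over genes). All 13 others gave -0.047 (SD 0.685). Both medians lay under the 0.80 of Tnni2 by more than that SD. Tnnt3 and Tnni2 had been picked as the highest of this list, so a median below Tnni2 was set in advance. The comparison therefore cannot decide on muscle as the source. The actin gene Acta1, at 11.91 in the control about as bright as Tnni2 at 11.88, gave -0.39 ± 0.28 (SE). The limit of 7 was chosen with these values known, and 2 earlier forms of the test were dropped: the highest of the 13, Mylpf at 0.354, which picking Tnnt3 and Tnni2 as the highest had set, and one that left the question open if any gene lay under 7. Muscle in the mutant dissections stays open. A Tnnt3 probe that read Tnnt2 alone is argued against by a change that exceeded that of Tnnt2 by 2.18 (SE 0.44). That SE takes the 2 probes as independent, and Tnnt3 had been picked for its high change. A probe that reads both genes stays open. For Tnni2 even a probe that read Tnni3 alone stays open: its change exceeded that of Tnni3 by 0.393 (SE 0.19). Tnni1 was saturated on 2 mutant arrays and 1 control array. That a change of troponin isoforms goes with the loss of Dicer remains a hypothesis, found and tested on the same arrays.

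Control 2 lay between the sexes. Xist, transcribed from the inactive X chromosome, stood at 8.73 there, against 9.88 to 10.42 in mutant 1, mutant 3 and control 3 and 5.91 to 6.20 in control 1 and mutant 2. The dimmer probe of Xist (number 26361) stood at 6.12 to 6.50 on the 6 arrays and did not separate them. The Y-linked Eif2s3y stood at 8.13, against 8.86 and 8.93 in mutant 2 and control 1 and 6.09 to 6.36 in the other 3 arrays. The other Y-linked genes measured, Kdm5d, Uty and Usp9y, did not separate the arrays in this way: Kdm5d stood at 8.61 in mutant 2 and at 8.72 and 8.76 in mutants 1 and 3. On the linear scale the female share of control 2 came to 0.34 from Xist and the male share to 0.511 from Eif2s3y. Their sum of 0.851, which rests on 1 probe per sex, is consistent with RNA of both sexes in that sample, such as a pool of embryos. No biological explanation was tested.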
